A study of Pimephales promelas with 40 samples.

How the data were processed

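The data were 40 single-colour (Cy3) Agilent arrays of total RNA from whole fathead minnow larvae. Per the labels, larvae 2 days old from a single batch were acclimated for 24 h and exposed for 7 days in beakers of 10 fish and 200 mL with daily renewal of 80% of the water. Each concentration had 5 beakers, 4 of which gave an array each from 4 larvae, so replicates are separate beakers. A 600 mg/L target dose is named by the labels and was not analysed here. The labels place the start of both exposures shortly after irradiation; they do not say in which order beakers were sampled or RNA was extracted and labelled. Groups and replicate numbers were taken from the sample titles.

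The intensity values are the scanner outputs deposited by the authors, made per the file headers with Agilent Feature Extraction 10.7.3.1 under its single-colour protocol; gProcessedSignal is background-corrected by that software and not normalized between arrays. The authors also deposited a table of log2 values for the same arrays. Set against the scanner values, it equalled the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 40 arrays and running in the same direction (lowest r over 40 arrays 0.9999). Its column medians lay between -0.068 and 0.054, and its scale, centring and direction are thus known from the data. It was used as an alternative.

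Each array held 62372 spots, 61053 of them not controls, for 49849 distinct probes. Here, log2 of the processed signal minus the array's 75th percentile was the normalised value. Spots marked as outliers by the scanner software were left out, between 90 and 176 per array, and spots of a probe were averaged. Signal over background sets the depth of an array: the 75th percentile of the processed signal was between 671.5 and 1093 and the median coefficient of variation of repeated spots between 5.34% and 8.02%. A probe was tested if it was well above background on all 4 arrays of at least 1 group, which kept 36831 probes. A probe well above background on no array of a group has only a bound there: the fold given is the brighter group's mean against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal.

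Probe names are those of the array's design: 8524 begin with CONTIG, 26117 with SINGLET and 15208 with UF_Ppr. The files do not pair them with genes, and 0 of the 49849 matched the table of gene symbols and accessions used here. The tests of gene lists and tissue markers fixed before the data were examined were therefore not run, and the rule for named genes (the largest changes among called genes with the treated arrays all on one side of the control mean) was applied with its limit of 2 probes that rose and 2 that fell per comparison. Where no probe was called, the probes with the smallest unadjusted p are given as values.

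Group means of the 10 groups were fitted to all 40 arrays with limma 3.58.1 in R 4.3.3, and contrasts were tested with eBayes and Benjamini-Hochberg adjustment at 0.05 within each contrast. The fit left 30 residual degrees of freedom, against 6 in a fit of 2 groups. Contrasts were each dose against 0 mg/L within a series, the series against each other at each dose, the interaction at each dose, and a linear trend over the rank of the dose with its difference between series. Tests are two-sided. The median change over all tested probes was under 0.1 on the log2 scale in each contrast. The permutation test of detection between the series used 100000 resamples. Counts of probes were set against 35 splits or 100 reassignments of the arrays, the 0 mg/L difference against 70 signed splits, and components against 1000 reassignments.

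The alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, the deposited log2 table, no filter and a filter requiring detection on all 40 arrays (27833 probes), slide as a block, the replicate number as a block, array weights, a trended robust variance prior, keeping marked spots, fitting only the groups compared, pooling the 0 mg/L arrays of both series, log2(dose + 1) as the trend's score, and leaving out each array. Added after the data were seen were the mean difference over 5 doses, the difference at 7 mg/L against the other doses, a block of slides in which 2 arrays of slide 4 form their own batch, and a fit with every signal under an array's detection floor, its lowest signal among probes well above background, raised to that floor. The normexp alternative used the median spot signal, since the files hold no mean signal column. Slide and scan coincide: each of the 5 slides held 8 arrays and was scanned once. The slide of each array, and its row on the slide (1 or 2), are known from the scanner output. Row was in no fit, although the rows differed in array quality. The share of spots well above background lay between 72.3% and 84.3% in row 1 and between 69% and 79.8% in row 2. The median coefficient of variation lay between 6.69% and 8.02% in row 1 and between 5.34% and 7.34% in row 2.

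The fit was tested on simulated data, in which residuals of the real arrays were shuffled between arrays and 200 of 36763 probes changed by known amounts. For UV-treated 200 against 0 mg/L, 16.8% of probes changed by 0.5 log2 units, 57.6% of those changed by 1, 75.4% by 1.5 and 87% by 2 were recovered, and a median of 2.99% of the calls were false. The number of false calls varied over the 10 simulations. It had a median of 3.5 and reached 21 here, and it reached 40 for parent 200 against 0 mg/L. For the interaction at 200 mg/L the shares were 5%, 33.6%, 60.2% and 73.8%, so that the interaction has less power than the comparisons within a series. A first requirement on the share recovered at the largest change was not met by the interaction and was replaced by requirements on bias (estimate within 0.1 of the true change, as a ratio) and on the share of false calls.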

Results

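Gene expression was measured in whole larvae of the fathead minnow, Pimephales promelas, a small freshwater fish used in toxicity testing. The larvae were kept for 7 days in water with 1-methyl-3-nitroguanidine (MeNQ), a nitroguanidine compound of insensitive munition formulations, or in water with MeNQ stock that had been irradiated with ultraviolet (UV) light. Each of the 2 series, called parent and UV-treated here, had nominal doses of 0, 7, 22, 67 and 200 mg/L. Each of the 10 groups held 4 arrays, every array from 4 larvae of a separate beaker, which gave 40 arrays in all. Per the labels, the stock measured 6140 mg/L before irradiation and 5940 mg/L of MeNQ after it, so that 96.7% of the MeNQ remained, and the stocks were diluted in dechlorinated tap water. The labels state UV exposure as 4 h in one place and 6 h in another. They do not say whether the 0 mg/L water of the UV-treated series had been irradiated. The comparisons ask how larvae responded to each solution and whether the responses to parent and UV-treated MeNQ differed.

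The arrays carried 49849 distinct probes, of which 36831 were well above background on all 4 arrays of at least 1 group and were tested. On single arrays, between 69% and 84.3% of the spots were well above background, and no spot was saturated. Replicate arrays correlated across probes with r between 0.9501 and 0.9807, and arrays of different groups with r up to 0.9821, so that replicates were not set apart by this measure. The probes are named after assembled sequences and the files do not pair them with genes, so that results are given by probe identifier, and a count of probes is not a count of genes. Of the 225 probes called in the UV-treated series at 200 mg/L, some followed each other so closely over the 40 arrays that they formed 205 profile groups at a residual correlation above 0.9. The number of arrays, 4 per group, limits the precision.

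At 200 mg/L the UV-treated series differed from its own 0 mg/L group in 225 probes, of which 58 rose and 167 fell (limma, adjusted p under 0.05). The median size of these changes was 0.76 on the log2 scale, and 69 of the probes changed by more than 2-fold. The largest rises were those of CONTIG8382, which was 4.15-fold higher (log2 change 2.05, SE 0.31, adjusted p = 0.000651), and UF_Ppr_AF_111151, which was 4.02-fold higher (log2 change 2.01, SE 0.32, adjusted p = 0.000932). Both rose in 4 of 4 arrays. Their residuals correlated at r = 0.937 over the 40 arrays, so these are not separate findings. CONTIG8382 lay at -2.97 ± 0.43 (SD, n = 4) on the normalised log2 scale in the UV-treated 0 mg/L group, at -1.76 ± 0.27 (SD, n = 4) at 67 mg/L and at -0.91 ± 0.44 (SD, n = 4) at 200 mg/L. In the parent series it lay at -3.18 ± 0.18 (SD, n = 4) at 0 mg/L and at -2.36 ± 0.70 (SD, n = 4) at 200 mg/L, a log2 difference of 0.83 (SE 0.31, adjusted p = 0.517) that did not pass. The difference between its changes in the 2 series, 1.23 (SE 0.44, adjusted p = 0.512), did not pass either.

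The largest fitted falls were those of SINGLET_29569 and UF_Ppr_AF_102674, both dim at 200 mg/L, so that their order among the falls is not known. SINGLET_29569 had a fitted change of -3.32 on the log2 scale (SE 0.46, adjusted p = 0.00014), but only 1 of the 4 arrays at 200 mg/L held it well above background, and with signals raised to the detection floor it fell by 2.30 (SE 0.32, adjusted p = 0.000161). SINGLET_12388, well above background on all arrays of both groups, fell by 2.48 (SE 0.30, adjusted p = 1.75e-05). UF_Ppr_AF_102674 was not well above background on any array at 200 mg/L and was at least 5.86-fold lower there than at 0 mg/L (adjusted p = 3.61e-06). These 3 probes lay lower in 4 of 4 arrays. In the parent series the log2 differences of SINGLET_29569 and UF_Ppr_AF_102674 at 200 mg/L were -0.67 (SE 0.46, adjusted p = 0.737) and -0.72 (SE 0.34, adjusted p = 0.591). With signals raised to the detection floor the changes in the 2 series differed by -1.62 (SE 0.45, adjusted p = 0.3) and -1.82 (SE 0.45, adjusted p = 0.221), and neither passed; UF_Ppr_AF_102674 had passed (adjusted p = 0.0337) on signals under background.

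The number of calls at 200 mg/L changed with the arrays in the fit. Fitted with limma on the 8 arrays of the comparison alone, with 6 residual degrees of freedom in place of 30, 0 probes passed and 3261 had an unadjusted p under 0.05. Against the 8 pooled 0 mg/L arrays of both series 961 passed, but that is another contrast, which takes in the difference between the series at 0 mg/L. The count was 148 without UV-treated 0 mg/L replicate 2, 135 without UV-treated 0 mg/L replicate 3, 116 without UV-treated 200 mg/L replicate 3 and 149 without UV-treated 200 mg/L replicate 4. A block for slide left 210 probes, 155 of them among the 225. Both groups were present on slides 2 and 4 only, where the median change of the 225 probes in the called direction was 0.777 and 0.793. The probes were picked on these same arrays, here and in the other comparisons within slides unless stated, which favours the called direction.

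**Figure D1:**
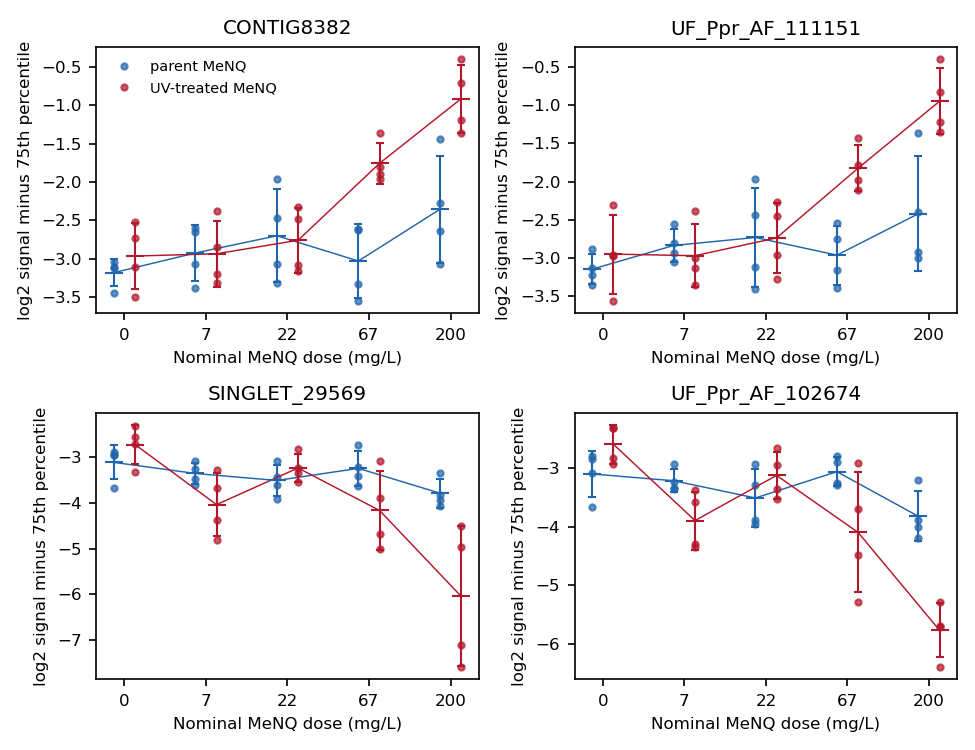
Normalised log2 signal (vertical axis, log2 processed signal minus the array's 75th percentile) of 4 probes by nominal dose in mg/L (horizontal axis, equally spaced), for parent MeNQ in blue and UV-treated MeNQ in red; points are arrays, dashes are group means and bars are ± 1 SD (n = 4). CONTIG8382 and UF_Ppr_AF_111151 lie highest in the UV-treated 200 mg/L group, and SINGLET_29569 and UF_Ppr_AF_102674 lie lowest there, the latter below the level of detection.

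No probe passed at the lower doses of the UV-treated series. With limma, 0 probes were called at 7, 22 and 67 mg/L, and 2927, 1070 and 2148 probes had an unadjusted p under 0.05, where 1842 of 36831 are expected by chance. The 58 probes that rose at 200 mg/L had a median log2 change of 0.07 at 7 mg/L, 0.13 at 22 mg/L, 0.28 at 67 mg/L and 0.61 at 200 mg/L. The 167 probes that fell had medians of -0.21, -0.20, -0.33 and -0.86 at these doses. These medians share their 0 mg/L arrays and the probes were picked at 200 mg/L. In the contrast with the pooled 0 mg/L arrays of both series, 661 probes passed at 7 mg/L and 57 at 67 mg/L. Without UV-treated 7 mg/L replicate 4, 2 probes passed at 7 mg/L, and without UV-treated 0 mg/L replicate 1 or 3, 1 passed at 67 mg/L; in fits of the 8 arrays alone 1 passed at 22 mg/L and 4 at 67 mg/L.

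Over the 5 doses in rank order, 706 probes had a trend in the UV-treated series, of which 374 rose and 332 fell. CONTIG8382 rose by 0.53 (SE 0.07, adjusted p = 6.48e-05) and UF_Ppr_AF_111151 by 0.52 (SE 0.07, adjusted p = 0.000135) on the log2 scale per dose step. SINGLET_29569 and SINGLET_41894 had the steepest fitted falls, but at 200 mg/L only 1 and 0 of the 4 arrays held them well above background. With signals raised to each array's detection floor, a setting added after the data were seen, SINGLET_29569 fell by 0.48 per step (SE 0.07, adjusted p = 0.000309), and SINGLET_41894 had a slope of -0.25 (SE 0.08, adjusted p = 0.107) that did not pass. The probes that rose over the ranks had a median change against 0 mg/L of -0.0881 at 7 mg/L, where 29.1% lay above 0 mg/L, and of 0.126, 0.258 and 0.359 at 22, 67 and 200 mg/L. Those that fell had medians of -0.112, -0.164, -0.342 and -0.672. The probes were picked on these arrays. Of the 225 probes called at 200 mg/L, 206 were also called for the trend, which includes the same arrays.

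The number of probes in the trend moved with the processing. It was 454 under quantile normalization and 1087 under normexp background correction. It was 552 with slide as a block, 478 of them among the 706, and the median slope in the called direction was between 0.0914 and 0.165 within slides 1, 2, 4 and 5; slide 3 held UV-treated arrays of 1 dose only. The count was 268 without UV-treated 0 mg/L replicate 2, 363 without UV-treated 0 mg/L replicate 3, 405, 288 and 411 without UV-treated 200 mg/L replicates 2, 3 and 4.

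**Figure D2:**
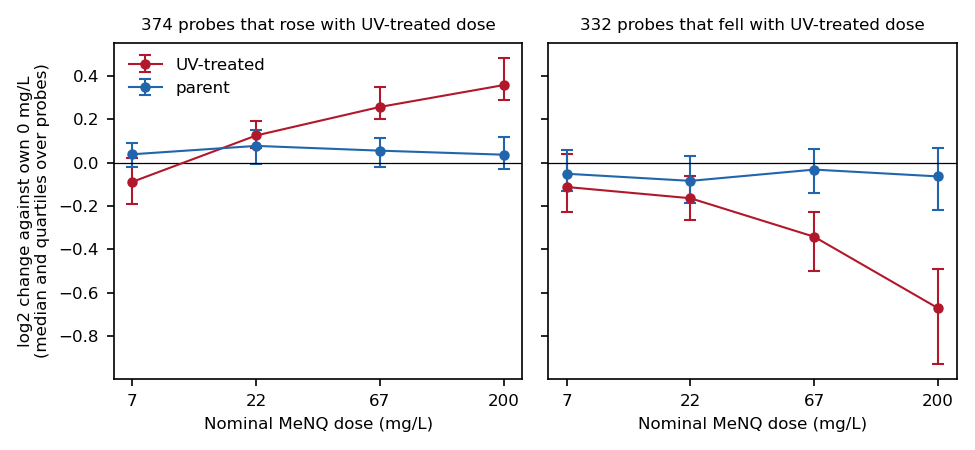
Median log2 change against the 0 mg/L group of the same series (vertical axis) by nominal dose in mg/L (horizontal axis, equally spaced), over the 374 probes that rose and the 332 that fell with UV-treated dose; points are medians, bars span the quartiles over probes. At 7 mg/L the UV-treated median of the probes that rose was below 0. At 200 mg/L the medians were 0.359 and -0.672 in the UV-treated series and 0.0372 and -0.0631 in the parent series; the probes were chosen on the UV-treated arrays.

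In the parent series no probe passed at any dose. With limma, 0 probes were called at 7, 22, 67 and 200 mg/L, and 1028, 1206, 1237 and 3028 probes had an unadjusted p under 0.05. The dose trend also called 0 probes, with 2982 at an unadjusted p under 0.05. The smallest unadjusted p values at 200 mg/L belonged to SINGLET_37837, with a log2 difference of -0.70 (SE 0.13, adjusted p = 0.227), and SINGLET_594, with a log2 difference of -0.63 (SE 0.13, adjusted p = 0.227). Among probes that lay higher at 200 mg/L, SINGLET_6254, well above background on 2 of 4 arrays at 0 mg/L, had a log2 difference of 1.16 with signals raised to the detection floor (SE 0.26, adjusted p = 0.187) and CONTIG7051 one of 0.68 (SE 0.16, adjusted p = 0.237). The median 95% interval of a change reached 0.425 on the log2 scale to either side. In simulated data built from these arrays, 54.8% of probes changed by 1 log2 unit and 20.6% of those changed by 0.5 were recovered for this comparison, so that small changes, or changes of single probes, could have been missed. Without parent 200 mg/L replicate 4, 2 probes passed at 200 mg/L and 2 in the trend, which called 1 without parent 67 mg/L replicate 1 or parent 200 mg/L replicate 1. In fits of the 8 arrays alone 4 probes passed at 200 mg/L and 2 at 7 mg/L.

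The 2 series were then compared at each matched dose. The UV-treated arrays differed from the parent arrays in 38 probes at 0 mg/L (3 higher and 35 lower), 2035 at 7 mg/L (740 higher and 1295 lower), 347 at 22 mg/L (74 higher and 273 lower), 44 at 67 mg/L (2 higher and 42 lower) and 209 at 200 mg/L (41 higher and 168 lower). At 0 mg/L, where no MeNQ was added, CONTIG6384 was 1.72-fold higher (log2 difference 0.78, SE 0.15, adjusted p = 0.0434) and CONTIG5166 1.41-fold higher (log2 difference 0.50, SE 0.10, adjusted p = 0.0421) in the UV-treated series, each in 4 of 4 arrays. SINGLET_47438, well above background on 1 of 4 UV-treated arrays, was lower by a log2 difference of -1.40 with signals raised to the detection floor (SE 0.24, adjusted p = 0.0197), and UF_Ppr_AF_100643, not well above background on any UV-treated 0 mg/L array, was at least 2.08-fold lower (adjusted p = 0.0434). Of the 38 probes, 26, 16, 2 and 1 were also called at 7, 22, 67 and 200 mg/L, in the same direction. Independent lists would share 1.29, 0.265, 0.0401 and 0.163 probes in the same direction. These are not valid chance levels, since each probe's residual spread came from all arrays and slide was not in the fit. Only the group means compared share no array between doses.

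The calls at 0 mg/L were the least stable of these. A block for slide left 0 probes in limma and 2733 had an unadjusted p under 0.05, and the count was 0 without parent 0 mg/L replicates 1 or 2 or UV-treated 0 mg/L replicates 2 or 4, 3 and 20 without UV-treated and parent 0 mg/L replicates 3, and 67 and 62 without UV-treated replicate 1 and parent replicate 4. Both groups were present on slide 4 only, with 1 array each, where the median difference of the 38 probes in the called direction was 0.51; since the probes were picked on these arrays, this value says little about the difference within a slide.

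At 7 mg/L the UV-treated arrays had SINGLET_45167 8.22-fold higher (log2 difference 3.04, SE 0.52, adjusted p = 0.00108) and CONTIG4274 7.27-fold higher (log2 difference 2.86, SE 0.51, adjusted p = 0.00133). CONTIG4169 and SINGLET_5972 were well above background on 3 and 1 of the 4 UV-treated arrays and lower by a log2 difference of -3.90 (SE 1.01, adjusted p = 0.0188) and -2.06 (SE 0.55, adjusted p = 0.023) with signals raised to the detection floor. Without UV-treated 7 mg/L replicate 2 the count of 2035 became 870, and without parent 7 mg/L replicate 3 it became 1114. The fit of the 8 arrays alone called 1 probe. A block for slide left 1805, and on slide 3, the only slide with both groups, the median difference of the 2035 probes in the called direction was 0.519.

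At 22 mg/L SINGLET_3504 was 4.25-fold higher (log2 difference 2.09, SE 0.48, adjusted p = 0.0312) and SINGLET_6332 4.03-fold higher (log2 difference 2.01, SE 0.50, adjusted p = 0.0441), while SINGLET_33341 and UF_Ppr_AF_104079 were well above background on 2 and 1 of the 4 UV-treated arrays and lower by -1.82 (SE 0.38, adjusted p = 0.022) and -1.29 (SE 0.29, adjusted p = 0.0281) with signals raised to the detection floor. At 67 mg/L UF_Ppr_AF_105140 was 1.71-fold higher (log2 difference 0.77, SE 0.14, adjusted p = 0.0194) and CONTIG10974 1.63-fold higher (log2 difference 0.70, SE 0.14, adjusted p = 0.0307), with residuals correlated at r = 0.892, while SINGLET_33343 was lower by -1.99 (SE 0.38, adjusted p = 0.0201) and SINGLET_33341, well above background on 3 of 4 UV-treated arrays, by -2.29 with signals raised to the detection floor (SE 0.38, adjusted p = 0.0168); their residuals correlated at r = 0.805, so neither pair is 2 separate findings. Blocked for slide, the counts were 155 at 22 mg/L and 2 at 67 mg/L. Within slides 2 and 5 the median difference of the 347 probes in the called direction was 0.873 and 0.62, and within slides 1 and 2 that of the 44 probes was 0.596 and 0.904. Under quantile normalization the counts were 61 higher and 129 lower at 22 mg/L, and 2 higher and 11 lower at 67 mg/L. At 22 mg/L the count was 67, 58, 120 and 188 without parent replicates 1 to 4, and 228, 104 and 18 without UV-treated replicates 2, 3 and 4. At 67 mg/L it was 0, 5 and 120 without parent replicates 2, 3 and 4, and 26, 0, 0 and 3 without UV-treated replicates 1 to 4. The fits of the 8 arrays alone called 0 (5595 at an unadjusted p under 0.05) and 1.

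At 200 mg/L UF_Ppr_AF_117028 was 2.79-fold higher (log2 difference 1.48, SE 0.30, adjusted p = 0.0154) and UF_Ppr_AF_111151 2.78-fold higher (log2 difference 1.48, SE 0.32, adjusted p = 0.0215) in the UV-treated arrays. Most of the rise of UF_Ppr_AF_117028 came from UV-treated replicates 2 and 3, both on slide 4, at -1.352 and -1.365. Replicates 1 and 4 lay at -2.939 and -3.224, against a parent mean of -3.70 ± 0.44 (SD, n = 4). SINGLET_12388 was lower by -2.79 (SE 0.30, adjusted p = 4.62e-06) in 4 of 4 UV-treated arrays. SINGLET_41894, not well above background on any UV-treated array, was also called (adjusted p = 0.00188), but not with signals raised to the detection floor (log2 difference -0.92, SE 0.37, adjusted p = 0.346). A block for slide left 271 probes, and within slides 2, 4 and 5 the median difference of the 209 probes in the called direction was 0.578, 1.08 and 0.727. The count was 122, 82 and 126 without parent replicates 1, 2 and 4, and 124, 65 and 130 without UV-treated replicates 2, 3 and 4. The fit of the 8 arrays alone called 0, with 2937 at an unadjusted p under 0.05.

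Averaged over the 5 doses, a contrast chosen after the single doses had been seen, the UV-treated series differed from the parent series in 6264 probes, 1959 higher and 4305 lower. SINGLET_11152 was 3.04-fold higher (log2 difference 1.61, SE 0.28, adjusted p = 0.000115) and CONTIG4274 3.02-fold higher (log2 difference 1.59, SE 0.23, adjusted p = 1.03e-05), while SINGLET_33341, dim in some UV-treated groups, was lower by -2.01 with signals raised to the detection floor (SE 0.17, adjusted p = 8.33e-09) and SINGLET_33342 by -1.99 (SE 0.21, adjusted p = 2.15e-07), each in the same direction at 5 of 5 doses. SINGLET_33341 lay at -2.79 ± 0.38 (SD, n = 4) in the parent and -4.19 ± 0.16 (SD, n = 4) in the UV-treated 200 mg/L group. The residuals of SINGLET_33341 and SINGLET_33342 correlated at r = 0.845. The median size of the 6264 differences was 0.30 on the log2 scale, and 47 were larger than 2-fold. A block for slide left 5583 probes, 5121 of them among the 6264. In probes called without a given slide, the median difference on that slide in the called direction was 0.186, 0.379, 0.341, 0.134 and 0.29 on slides 1 to 5. Under quantile normalization 2306 probes were higher and 2850 lower, so that the share of lower probes was 55.3% in place of 68.7%.

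**Figure D3:**
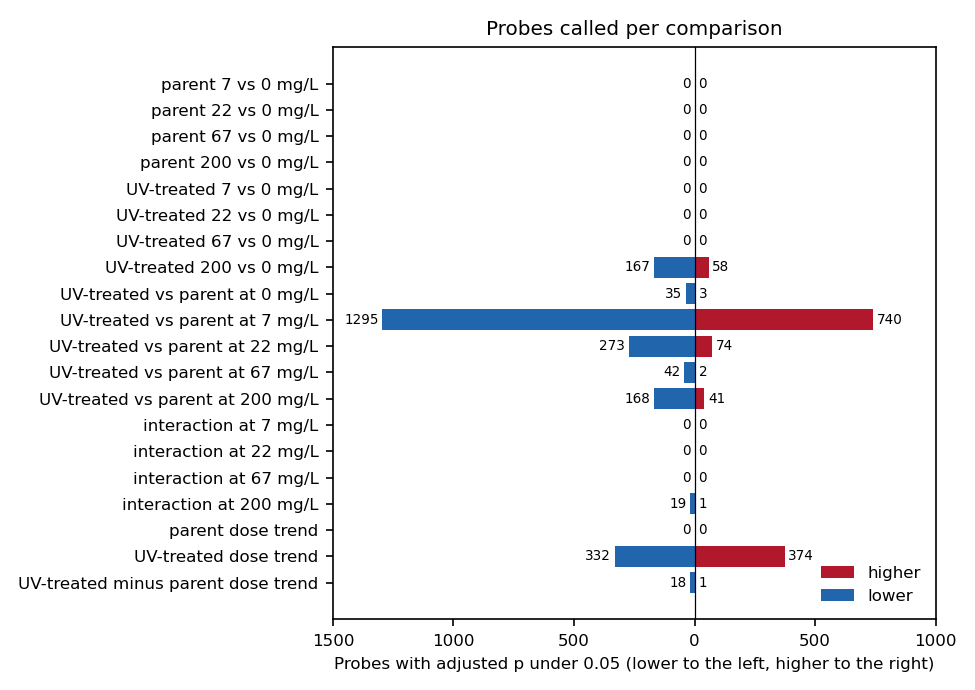
Number of probes with an adjusted p under 0.05 in limma (horizontal axis, higher to the right in red and lower to the left in blue) for each comparison fixed before the data were examined (vertical axis). The parent series called 0 probes against its own 0 mg/L group at each dose, the UV-treated series 58 and 167 at 200 mg/L, and the 2 series differed from each other at all 5 doses in this fit, which has no term for slide, most at 7 mg/L.

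Whether the change from 0 mg/L differed between the series was tested as an interaction. At 7, 22 and 67 mg/L limma called 0 probes, with 2131, 996 and 1317 at an unadjusted p under 0.05; the median 95% interval of these differences reached 0.601 on the log2 scale to either side, which does not show that the series responded alike. At 200 mg/L 20 probes were called, 1 with a higher and 19 with a lower change in the UV-treated series. UF_Ppr_AF_108069 had a higher change by 1.00 (SE 0.20, adjusted p = 0.0404), SINGLET_10844, well above background on 3 of 4 UV-treated arrays, a lower one by -2.48 with signals raised to the detection floor (SE 0.38, adjusted p = 0.00439) and SINGLET_12388 a lower one by -2.59 (SE 0.42, adjusted p = 0.00744). SINGLET_12388 lay at -0.27 ± 0.50 (SD, n = 4) and -2.75 ± 0.43 (SD, n = 4) in the UV-treated 0 and 200 mg/L groups, and at -0.07 ± 0.29 (SD, n = 4) and 0.04 ± 0.54 (SD, n = 4) in the parent groups. Over the 20 probes the median log2 change was -1.35 in the UV-treated and 0.21 in the parent series.

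These 20 calls were not stable. In 10 simulations with known changes, the number of false calls for this interaction had a median of 1.5 and reached 15. Blocked for slide, 10 passed, and 0 passed (2251 at an unadjusted p under 0.05) when 2 arrays of slide 4 that lay apart from the others of that slide were made a separate batch, a setting added after the data were seen; SINGLET_12388 then had a difference of -2.76 at an adjusted p of 0.0593. In the fit of the 16 arrays alone 0 passed, with 2510 at an unadjusted p under 0.05 and 12 residual degrees of freedom. The count was 5, 10 and 8 without parent 0 mg/L replicates 1, 3 and 4, 6, 7 and 11 without parent 200 mg/L replicates 1, 2 and 4, 12, 12 and 7 without UV-treated 0 mg/L replicates 1, 3 and 4, and 11 and 6 without UV-treated 200 mg/L replicates 1 and 3. Slide 4 was the only slide with all 4 groups, and the median difference of the 20 probes there was 1.82 in the called direction.

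The difference in dose trend between the series called 19 probes, 1 with a higher and 18 with a lower slope in the UV-treated series, and 13 of them were among the 20. SINGLET_12388 had a difference in slope of -0.60 per dose step (SE 0.09, adjusted p = 0.00568) and SINGLET_49994 one of 0.15 (SE 0.03, adjusted p = 0.0489). With signals raised to the detection floor 15 probes passed, all with a lower slope; SINGLET_49994 then had an adjusted p of 0.0516, and SINGLET_41894, called on signals under background, a difference of -0.32 (SE 0.12, adjusted p = 0.354). A block for slide left 18 probes, and leaving out 1 array gave 10 without parent 0 mg/L replicate 1, 12 without UV-treated 200 mg/L replicate 3 and at most 23.

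Across the 36831 probes, which are not independent replicates, the changes from 0 mg/L in the 2 series correlated with r = -0.125 at 7 mg/L, 0.0359 at 22 mg/L, 0.0234 at 67 mg/L and 0.0688 at 200 mg/L. Spearman's rho was -0.113, 0.0496, 0.0859 and 0.108. In simulated data without any effect such correlations had an SD of 0.222, so over all probes none of the 4 stood apart from 0. Over the 225 probes called in either series at 200 mg/L, all of them in the UV-treated series, r was 0.351, and no simulated value was computed for such a selection. Of the 225 probes called in the UV-treated series at 200 mg/L, 130 had a parent change of the same sign, with a median of 0.0382 in the called direction against a median size of 0.762 in the UV-treated series, in which they had been picked.

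The arrays separated mainly by slide. The first principal component held 19.7% of the variance, of which slide explained 77% and group 4.67%. The second held 8.06%, of which series explained 41% and slide 37.4%, each taken alone. The second component is thus not free of slide. After groups were accounted for, 5195 of the 36831 probes differed between slides. The parent series had 4, 3, 6, 3 and 4 arrays on slides 1 to 5 and the UV-treated series 4, 5, 2, 5 and 4.

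**Figure D4:**
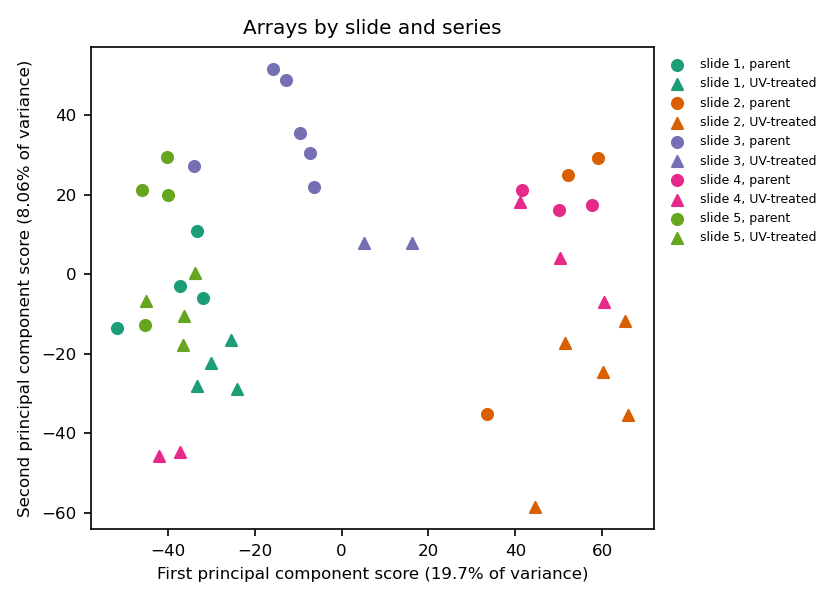
Scores of the 40 arrays on the first (horizontal axis, 19.7% of the variance) and second principal component (vertical axis, 8.06%); colour marks the slide, circles the parent and triangles the UV-treated series. On the first component the arrays of slides 1 and 5 lie below 0 and those of slide 2 above 0, while slide 3 spreads from -33.97 to 16.18 and 2 UV-treated arrays of slide 4 lie at -42.04 and -37.25, apart from its others. The series separate more along the second than along the first, but slide also explains part of the second.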

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

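The tests of slide layout, solution content (with and without slide in the fit), signal level, a deviating array, slide or scan, treatment group, column position, the splits with slide in the fit and the highest of the 5 doses were chosen after the results they bear on had been seen; the counts of other splits and the contrast of 7 mg/L with the other doses were set out before they were computed.

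Of 115 groups of 4 arrays examined for a value far from the others, 3 were found, where chance gives about 5.75. Parent 67 mg/L replicate 2 had a 75th percentile of the signal of 809 against 910 to 929 in the others. Parent 67 mg/L replicate 4 had a score of -13.6 on the second principal component against 22.1 to 29.4. Parent 0 mg/L replicate 3 had UF_Ppr_AF_108069 at 0.0248 against -0.209 to -0.178.

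The change from 0 to 200 mg/L differed between the series in 20 probes, and the dose trend in 19. For the first, 3 of 100 reassignments of the 0 and 200 mg/L labels within series gave as many in the fit without slide. Such reassignments assume no dose effect in either series, so they do not exclude chance for a difference between the effects. The highest other reassignment gave 139. That reassignment exchanged the 2 doses in the UV-treated series only, and so measured the sum of the changes in both series in place of their difference. With slide in the fit 10 probes passed, 3 of 100 reassignments gave as many and the highest other gave 55, but 31 of 100 gave as many probes at an unadjusted p under 0.05 as the real 2248 (highest other 4545). With the 2 apart arrays of slide 4 as their own batch 0 passed, and 33 of 100 reassignments gave as many probes at an unadjusted p under 0.05 as the real 2251 (highest other 3983), so chance cannot be excluded there and the 20 calls stay open. For the trend difference, 1 of 100 reassignments, the real one, gave 19 and the highest other gave 1 in the fit without slide. Shuffled doses assume no trend in either series, so the count speaks against chance only under that assumption. For the interactions at 7, 22 and 67 mg/L, 33, 93 and 64 of 100 reassignments gave as many probes at an unadjusted p under 0.05 as the real 2131, 996 and 1317, with highest others of 4758, 3516 and 4101, so chance cannot be excluded.

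For UV-treated 200 against 0 mg/L, 2 of the 35 splits of the 8 arrays called as many probes as the real 225, and the highest other called 300, so chance cannot be excluded on this count. The split with 300 put the 4 arrays with a positive score on the first principal component against the 4 with a negative one: slides 2 and 4 against slides 1 and 5 and UV-treated 200 mg/L replicate 3 of slide 4. It thus follows the slides. Blocked for slide, the real split called 210 and was the only 1 of 35 to call as many, the highest other calling 15. When the 2 apart arrays of slide 4 formed their own batch it called 167, and the highest other 9. The row of an array on its slide was in no fit, and most 200 mg/L arrays lay in row 1 and most 0 mg/L arrays in row 2. The split by row, looked at after the results were seen, was among the 35. It called at most 15 probes with slide in the fit, which argues against row as the whole source. Row as part of the source, and row in the dose trend, were not tested. For the UV-treated dose trend 1 of 100 reassignments, the real one, gave 706 and the highest other gave 7, so chance can be excluded in the fit without slide. At the lower UV-treated doses, 11, 32 and 7 of 35 splits gave as many probes at an unadjusted p under 0.05 as the real 2927, 1070 and 2148 (highest others 4047, 5028 and 3393). In the parent series 27, 18, 30 and 3 of 35 splits did so at 7, 22, 67 and 200 mg/L, against the real 1028, 1206, 1237 and 3028 (highest others 3566, 2441, 2743 and 3559), and 8 of 100 reassignments for the parent trend (real 2982, highest other 4301). Chance cannot be excluded for any of these 8 counts.

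In fits without slide the UV-treated and parent series differed at every dose, in 38, 2035, 347, 44 and 209 probes from 0 to 200 mg/L, but blocked for slide 0 passed at 0 mg/L, where the groups share only slide 4, and 2 at 67 mg/L. Without slide in the fit, 1 of 35 splits, the real one, called as many probes at each dose, the highest others calling 1, 3, 1, 4 and 5. This share, 2.86%, is the smallest that 35 splits can give, and 5 doses were examined. At a single dose it thus argues against chance without excluding it. For the mean over 5 doses, 6264 probes, 1 of 100 reassignments called as many (highest other 1), so chance can be excluded for the mean. Neither the splits nor the reassignments separate slide from series. Slide as the whole source is argued against by the 81.8% of the 6264 probes that stayed called in the same direction with slide as a block. Signal level as the whole source of the mean difference is argued against by the 72.2% that stayed called so under quantile normalization. At single doses only 1 probe passed under quantile normalization at 0 mg/L and 13 at 67 mg/L. Signal level thus stays open at these doses. The share of spots well above background was 75.7% ± 4.55 (SD, n = 20) in the UV-treated and 76.7% ± 4.28 (SD, n = 20) in the parent series (permutation p = 0.442, two-sided). At 0 mg/L alone it lay between 70.4% and 74.8% on UV-treated and between 74.5% and 80.2% on parent arrays, which was not tested. MeNQ or its photoproducts as the whole source are argued against by the 0 mg/L arrays. In 4740 probes called for the mean difference over 7 to 200 mg/L, the median 0 mg/L difference in the called direction was 0.27. It lay above 69 of the 70 signed splits (highest other 0.221). With slide in the fit it was 0.208, again above 69 of 70 (highest other 0.172), and 88% of the probes had the called direction. On slide 4 alone, the only slide with both groups and with 1 array each, it was 0.0856, and 62.5% had the called direction. These splits were not made under quantile normalization. The residual spread behind these calls included the 0 mg/L groups, which favours the real split. The slide terms drew on the arrays that picked the probes. In 4465 probes called in a fit without slide or the 0 mg/L arrays the median was 0.279, for which no splits were made. What stays open, and was not tested, is anything else that ran with the series: the control water, the position or handling of the beakers, or the order of extraction and labelling.

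The most probes differed between the series at 7 mg/L, 2035 against 347 at the next highest dose. A single deviating array as the whole source is argued against by the lowest count without 1 array, 870 (without UV-treated replicate 2). Slide as the whole source is argued against by the 1805 probes with slide as a block, against at most 271 at the other doses. The row of an array on its slide was in no fit. At 7 mg/L, unlike the other doses, most UV-treated arrays lay in row 1 and most parent arrays in row 2. The split of these 8 arrays by row, looked at after the results were seen, was among the 35. It called at most 3 probes without slide in the fit. This argues against row as the whole source of the count, and row as part of it was not tested. A response specific to 7 mg/L stays open: the contrast of 7 mg/L with the mean of the other 4 doses called 0 probes in limma, but 4 with array weights and up to 5 without 1 array, so that the count of 0 does not hold in every setting. In that contrast 3582 probes had an unadjusted p under 0.05, a number that 3 of 100 reassignments of the doses reached (highest other 3840), but 7 mg/L had been picked as the most extreme dose. For the highest of the 5 doses 11 of 100 reassignments reached it (highest other 5622), and 200 mg/L against the other doses had 3546, so chance cannot be excluded. With slide in the fit 200 mg/L was highest with 3455, which 9 of 100 reassignments reached (highest other 5382), against 3004 at 7 mg/L. With the 2 apart arrays of slide 4 as their own batch 200 mg/L was again highest with 3503, against 3185 at 7 mg/L. That number was reached by 4 of 100 reassignments (highest other 4571). In these fits 7 mg/L was thus not the most extreme dose.

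The arrays separated mainly along the first principal component. The treatment group is argued against by the 4.67% of that component it explained, below the 21.5% that is the median of 1000 random reassignments. Slide or scan explained 77%, more than each of 1000 reassignments, and remains a candidate explanation. A fixed effect of column 3, which held the 2 apart arrays of slide 4, is argued against, since this column lay lowest on 1 of 5 slides. Column 1 had the lowest mean on slides 1, 2 and 3 (-41.83, 48.05 and -24.81), and an effect of other columns was not tested. Why these 2 arrays (UV-treated 22 mg/L replicate 2 and UV-treated 200 mg/L replicate 3) lay at -42.04 and -37.25 when the others of slide 4 lay between 40.95 and 60.42 was not tested.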

How the results depend on the processing

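The block of slides with 2 arrays of slide 4 apart, the detection floor, the mean over 5 doses and the contrast of 7 mg/L with the other doses were added after the data were seen. No called probe named in the text changed direction: of 583 refits of a named probe outside the leave-one-out fits, 488 kept their side of the threshold and 95 fell short of it. The called probes had been picked for large changes on these same arrays, so the lack of reversals says little about stability. Unless stated, the cause of a change between settings was not tested. Probes near background limit these arrays: the filter on dim probes sets how many tests are adjusted for. With signals raised to the detection floor each count stayed within 1.5 times its value, with 220 for UV-treated 200 mg/L, 215 of them among the 225, and 703 for the UV-treated trend, but SINGLET_41894 lost its 4 calls and 5 other named probes lost 1 call each.

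The fits of only the compared groups, which have fewer samples and so fewer degrees of freedom, gave 0 for UV-treated 200 mg/L and 1 and 4 for UV-treated 22 and 67 mg/L against 0, 4 and 2 for parent 200 and 7 mg/L, 4, 1, 0, 1 and 0 between the series at 0, 7, 22, 67 and 200 mg/L, and 0 and 1 for the interaction at 200 and 67 mg/L. The 8 pooled 0 mg/L arrays, which make another contrast, gave 961, 57 and 661 for UV-treated 200, 67 and 7 mg/L. Normexp gave 1 for UV-treated 67 mg/L, 1087 for the UV-treated trend and 12, 152 and 325 between the series at 0, 22 and 200 mg/L. Quantile normalization gave 454 for the trend and 1, 190, 13 and 137 at 0, 22, 67 and 200 mg/L. Without a filter, the trend had 467, the interaction 12, and the series differed in 4, 144 and 24 at 0, 22 and 67 mg/L; the strict filter gave 72 and 534 at 0 and 22 mg/L. Slide as a block gave 10 for the interaction at 200 mg/L and 0, 155 and 2 at 0, 22 and 67 mg/L; the split block gave 0 for the interaction, 397 for the trend and 0, 152 and 2 at these doses. Array weights gave 90, 994 and 221 at 0, 22 and 67 mg/L and 4 for 7 mg/L against the other doses, the robust prior gave 20 at 0 mg/L, and log2(dose + 1) gave 407 for the trend. Among the probes called in either series at 200 mg/L the changes correlated at 0.351 in place of 0.0688. These are fewer probes, all picked on the UV-treated arrays, and no simulated value was computed for them.

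The replicate number did not pair the arrays: residuals of arrays with the same number correlated at 0.0024 on average, and 14 of 40 arrays correlated best with their own number. The replicate block gave 78 between the series at 67 mg/L, 214 for UV-treated 200 mg/L, 672 for the UV-treated trend and 20 for the interaction.

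Leaving out 1 array gave 116 to 193 for UV-treated 200 mg/L, 268 to 901 for the UV-treated trend, 5 to 25 for the interaction at 200 mg/L, 10 to 23 for the trend difference, 0 to 67, 870 to 2017, 18 to 292, 0 to 120 and 65 to 268 between the series at 0, 7, 22, 67 and 200 mg/L, 0 to 5 for 7 mg/L against the other doses, 0 to 2 for UV-treated 7 mg/L, parent 200 mg/L and the parent trend, 0 to 1 for UV-treated 67 mg/L, and 5612 to 6382 for the mean over 5 doses. The remaining counts stayed at 0. Tests of gene lists and tissue markers, and their alternatives, were not run for want of gene names.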

Other observations

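The tests here were chosen after the main results had been seen. The differences between the series at the 5 doses, which share no arrays, resembled each other across probes. Over the 10 pairs of doses the correlation lay between 0.0572 (22 and 200 mg/L) and 0.387 (0 and 22 mg/L), with a mean of 0.201; in 100 reassignments of the series labels within doses the mean reached at most 0.137. Slide runs through all doses, and with slide in the fit the mean was 0.171 against at most 0.101 in the same reassignments, or 0.181 against 0.122 with 6 batches. In probes called for the mean over the other 4 doses, in fits without slide or the arrays of the dose itself, the median difference in the called direction was 0.279 at 0 mg/L (4465 probes, 92.7% of the called sign), 0.327 at 7 mg/L, 0.3 at 22 mg/L, 0.229 at 67 mg/L and 0.119 at 200 mg/L (6024 probes, 73.4%). SINGLET_33341, the named probe with the largest mean difference, had differences of -1.92, -2.65, -1.82, -2.29 and -1.39 at the 5 doses in order with signals raised to the detection floor, and was well above background on 2, 2 and 3 of the 4 UV-treated arrays at 7, 22 and 67 mg/L.

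Within a series, changes at 67 and 200 mg/L share their 0 mg/L arrays. Their correlation was 0.526 in the parent and 0.503 in the UV-treated series, against 0.535 (SD 0.111) in 20 simulations without any effect, and their covariance was 0.0515 and 0.0572 against 0.0662 (SD 0.0432). No excess over the shared controls was found in either series across all probes, although 706 probes had a trend in the UV-treated series.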
